A study of Homo sapiens with 12 samples.

How the data were processed

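Total RNA of primary human airway smooth muscle cells was sequenced by the authors after 4 h untreated, with IL-17A (100 ng/ml), with DEX (1 µg/ml) or with both, in 12 libraries, 3 a group. The deposited files hold 1 table a group, with 3 library columns and 1 group column, over 48162 Ensembl gene identifiers. The deposited values behave as RPKM, that is, the authors scaled reads by gene length and by the total of each library. Neither the headers nor the labels name this unit. It was read from the values: they are not whole, each library sums to 325579 to 338456, and within a gene the low values of all libraries are whole multiples of a step that scales with the inverse of gene length. The group column of each deposited RPKM table equals the mean of its 3 libraries to within 6.7e-07 and was not used further. The aligner, the read counter, the genome build, the annotation and the strand are not given in the sources used here, so no coordinates are printed.

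Whole reads were recovered from the steps of the values. The totals so found were 13.34, 13.63 and 16.38 M reads for untreated 1 to 3, 14.24, 13.72 and 12.91 M for IL-17A, 15.19, 36.84 and 13.09 M for DEX, and 15.17, 14.73 and 15.89 M for both treatments. With a tolerance of 0.02 reads, 12552 of the 12634 tested genes (99.35%) gave whole reads in every library. On simulated data, all 12 totals came back exactly, as did the reads of 99.19% of the 15854 genes (of 20000) with at least 3 libraries above 0. The simulated values were made with the gene lengths of GENCODE release 29, which were also used to find the totals. In the real data only 1154 recovered lengths equalled those of that release, so the simulation does not cover this mismatch. These totals set the depth: 3 reads of the gene CSF3, for example, correspond to 0.0487 to 0.139 RPKM depending on the library. Such limits cover counting error only.

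Symbols came from a name table for 33626 identifiers and, with GENCODE release 29 added, for 45342 (94.1%). GC content from that release was found for 97.6% of tested genes. XIST, TSIX and Y-linked genes, 483 identifiers in all, were left out of every test, table and plot. All 12 libraries were used.

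The planned test for counts was not used, because the deposited values are normalized, and it was not run on the recovered reads. The fallback planned for normalized values was taken: limma 3.58.1 in R 4.3.3, with trend, on log2(value + 1). Genes with a value of at least 1 in at least 3 libraries were kept, 12634 in all, of which 12325 had a symbol. A single fit held the 4 groups with 8 residual degrees of freedom, and gave 5 comparisons and the interaction (both minus IL-17A minus DEX plus untreated). Genes with a Benjamini-Hochberg adjusted p under 0.05 in a comparison count as changed; tests are two-sided. No block was used, since no label says that a replicate number marks a donor or a day. On simulated data the IL-17A comparison called 60.6%, 80.7% and 96.7% of genes changed by 1.5, 2 and 4-fold, with a mean of 8 false calls. The interaction called 30.8%, 69.4% and 90.6%, with 6.6 false calls. These simulations changed more genes than the real fits of both comparisons called, and drew the noise of each gene independently. In the real libraries 1 component held 38.7% of the variance within groups over all tested genes. The simulated rates may therefore not hold for these data.

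There were 14 gene lists and 4 cell type marker lists, tested with camera at a preset inter-gene correlation of 0.01 and adjusted over lists within a comparison; an estimated correlation and fry were alternatives. Lists needed 3 tested members. The lists, the tests, the filter, the alternatives fixed with the design and the rule for naming genes were fixed before the data were examined. The rule named, in each comparison, the 10 largest rises and the 10 largest falls among changed genes whose libraries do not overlap, whose mean log2(value + 1) is at least 1 and which have an ordinary symbol; 20 genes of interest; and up to 4 members of each list with the smallest p. Where all genes of a short count are listed, those outside the rule were chosen after their values were seen, as were the list members and low genes given as further examples.

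Alternatives fixed with the design were quantile normalization, no filter, a stricter filter (at least 5 in at least 6 libraries), pseudocounts of 0.1 and 5, the replicate number as a block, a fit of only the groups compared, stricter thresholds and leaving out each library in turn. After seeing the data 3 more were added: limma-voom on the recovered reads, removal of a lowess trend (span 0.3) over GC content and then gene length from each library, and leaving out IL17A 2 and untreated 2 together. Regroupings of the libraries were counted in full for 3 against 3 (10 splits) and drawn 100 times for the interaction. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9. Plots were drawn from the tables of results.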

Results

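RNA was sequenced from cultured primary human airway smooth muscle cells. The cells were kept for 4 h in 1 of 4 conditions: no addition (untreated), 100 ng/ml of the cytokine IL-17A, 1 µg/ml DEX, or IL-17A and DEX together. DEX is the usual abbreviation of dexamethasone, a synthetic glucocorticoid, and is the only name the labels give. Each condition had 3 libraries, 12 in all, and the design asks what IL-17A does, what DEX does, and whether DEX alters the response to IL-17A. The reads behind the deposited RPKM values (reads scaled by gene length and by the total of the library) came to between 12.91 and 16.38 M reads per library, except for DEX 2 with 36.84 M reads. In every library between 11799 and 12203 genes had a value of at least 1, and 12634 genes entered the tests. Spearman correlations between libraries of the same group, across genes, were 0.984 to 0.987 for untreated cells, 0.969 to 0.989 for IL-17A, 0.989 to 0.992 for DEX and 0.99 to 0.992 for both. The labels do not say whether the 3 libraries of a group are separate cultures or donors, so all p-values measure the spread between these samples, which may be technical.

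The untreated cells expressed genes of the contractile apparatus over a wide range. Tropomyosin TPM1 stood at 379 ± 16.9 RPKM (SD, n = 3), caldesmon CALD1 at 232 ± 16.3 (SD, n = 3), and TAGLN at 177 ± 15.3 (SD, n = 3). The smooth muscle actin ACTA2 stood at 22.2 ± 1.91 (SD, n = 3), and the smooth muscle myosin MYH11 at 0.297 ± 0.0596 (SD, n = 3). Of the marker lists for other cell types, the fibroblast list had 6 of 8 members above the expression filter, among them DCN at 305 ± 20.1 (SD, n = 3), which smooth muscle cells also express. The epithelial list had 1 of 11 members above it, MUC1, and no other member passed 0.634 RPKM in any library. The endothelial list had 1 of 8, TEK, with 6 others at 0.34 or less and 1 absent from the gene identifiers, and the leukocyte list had 0 of 10, with a highest value of 0.843.

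IL-17A alone was compared with untreated cells to find the genes that answer the cytokine. It raised above all the neutrophil-attracting chemokines. CXCL1 (ENSG00000163739) went from 3.28 ± 0.331 RPKM (SD, n = 3) to 92.6 ± 3.67 (SD, n = 3), a log2 change of 4.45 ± 0.08 (SE; adjusted p = 5.57e-12). CXCL6 (ENSG00000124875), a related chemokine, went from 1.85 ± 0.181 to 19.8 ± 2.17 (SD, n = 3 each; adjusted p = 3.35e-09). CXCL8 (ENSG00000169429), which codes for interleukin 8, went from 2.03 ± 0.398 to 19.1 ± 3.48 (SD, n = 3 each; adjusted p = 1.52e-06). The gene of the inhibitor-like NF-kB cofactor that IL-17A is known to induce, NFKBIZ (ENSG00000144802), went from 4.01 ± 0.303 to 25.1 ± 2.12 (SD, n = 3 each), and ZC3H12A (ENSG00000163874), which codes for an RNase that degrades cytokine transcripts, from 2.31 ± 0.519 to 12.3 ± 1.54 (SD, n = 3 each).

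In all, limma called 30 of 12634 genes changed at a Benjamini-Hochberg adjusted p under 0.05, of which 25 rose and 5 fell. At least 2-fold changes on the log2(value + 1) scale made up 13 of the rises and 2 of the falls. That scale understates the change of genes with low values. For genes named by the size of their change, the 3 values of 1 group lay wholly above the 3 of the other, which chance gives for 10% of genes. Complement C3, a protein of innate defence, rose by 1.56 ± 0.11 (SE) to 6.09 ± 0.806 RPKM (SD, n = 3). Mitochondrial superoxide dismutase SOD2, a classical NF-kB target, rose from 42.2 ± 2.19 to 123 ± 13.8 (SD, n = 3 each). The cytokine IL6 rose from 3.66 ± 0.336 to 12.4 ± 3.01 (SD, n = 3 each; adjusted p = 3.60e-04). CXCL3 rose by 1.51 ± 0.14 (SE) to 2.71 ± 0.451 RPKM (SD, n = 3). The monocyte chemokine CCL2 rose from 43.0 ± 2.05 to 82.4 ± 3.70 (SD, n = 3 each; adjusted p = 2.46e-04). The cytokine LIF, of the interleukin 6 family, rose by 0.98 ± 0.12 (SE; adjusted p = 0.00212). CCL7, another monocyte chemokine, was near the threshold (log2 change 1.11 ± 0.19, SE; adjusted p = 0.0331) and lost its call when 1 library was left out in 5 of the 6 cases.

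Smaller rises were called as well. SLC39A14, a zinc and iron transporter, rose by 0.89 ± 0.06 (SE; adjusted p = 3.16e-06), and the iron transporter SLC11A2 by 0.57 ± 0.09 (SE). TNFAIP6, which codes for a hyaluronan-binding secreted protein, rose from 5.77 ± 0.486 to 12.6 ± 0.749 RPKM (SD, n = 3 each). PAPPA, a protease of insulin-like growth factor binding proteins, rose by 0.74 ± 0.07 (SE), and the irritant-gated channel TRPA1 by 0.63 ± 0.11 (SE; adjusted p = 0.0411). The bradykinin receptor BDKRB2 rose by 0.41 ± 0.07 (SE), and NFKBIA, the gene of the main NF-kB inhibitor, by 0.39 ± 0.06 (SE; adjusted p = 0.00811). POU2F2, NAB1, GPRC5B, KRTAP1-5, the small nucleolar RNA SNORA71B and 1 pseudogene made up the rest of the 25. The 5 that fell were LBH (log2 change -0.40 ± 0.07, SE), the long noncoding RNA NEAT1 (-0.35 ± 0.05, SE), the pseudogene SNRPGP10, AP003392.2 and the unnamed gene ENSG00000268656. The reads of pseudogenes and of genes that overlap others may belong elsewhere, and the strand was not given in the sources used here.

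Of the 14 fixed gene lists, the chemokine and cytokine list moved most: 8 of 12 tested members rose and 0 fell over all genes, and 10 rose adjusted over the list alone (camera adjusted p = 2.83e-43, and 6.44e-06 with an estimated correlation). The NF-kB feedback and response list followed, with 3 of 22 risen (NFKBIZ, SOD2 and NFKBIA), 8 adjusted over the list alone, and an adjusted p of 1.06e-14 (0.000165 with an estimated correlation). The acute phase list had 1 of 7 risen, C3, and passed at 0.00275 (0.0371 with an estimated correlation). The prostanoid list (0 of 14 called; adjusted p = 0.0306) and the cell cycle list (0 of 22 called; median log2 change 0.04; adjusted p = 0.0435) passed too, but gave adjusted p = 0.0854 and 0.216 with an estimated correlation. The lists for IL-17 receptor signalling and mRNA stability, C/EBP and AP-1 factors, glucocorticoid-induced genes, contractile genes, extracellular matrix, MAP kinase phosphatases, circadian clock, interferon response, heat shock and fibroblast markers had adjusted p-values from 0.0569 to 0.853. Several genes often tied to IL-17A were not called: IER3, an immediate early gene (17.4 ± 3.86 to 28.4 ± 5.01 RPKM, SD, n = 3 each; limma adjusted p = 0.149), TNFAIP3, the gene of the A20 deubiquitinase (adjusted p = 0.763), and CEBPB, an acute phase transcription factor (adjusted p = 1). The receptor subunit IL17RA stood at 10.4 ± 0.539 and 9.83 ± 1.27 (SD, n = 3 each) and its adaptor TRAF3IP2 at 4.31 ± 0.106 and 4.44 ± 0.208 (SD, n = 3 each). Leaving out 1 library at a time gave 17 to 36 changed genes, with 17 without untreated 3 and 19 without untreated 1 or IL17A 3. Removal of a GC content and gene length trend from each library, an alternative chosen after seeing the data, raised the count to 97.

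**Figure D1:**
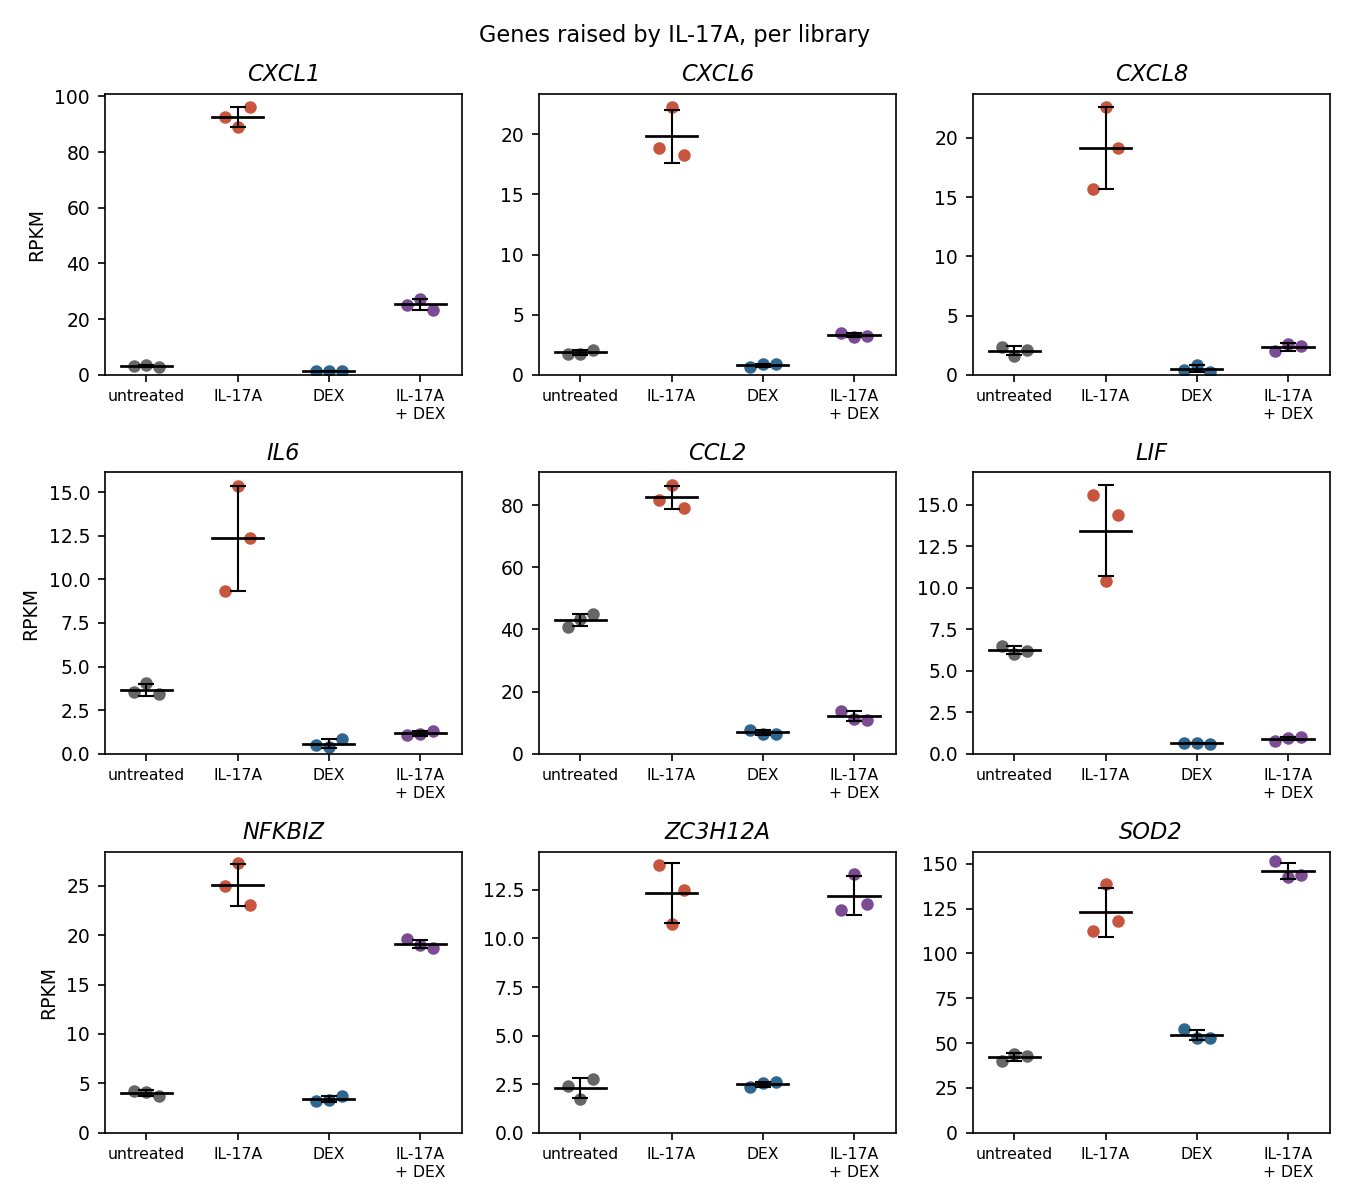
RPKM of 9 genes that IL-17A raised, in each of the 12 libraries (points), with the mean and SD of each group of 3 (line and bar). CXCL1, CXCL6, CXCL8, IL6, CCL2 and LIF were lower with IL-17A and DEX than with IL-17A alone, while ZC3H12A was at 12.3 and 12.2, and SOD2 was at 123 and 146.

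DEX alone was compared with untreated cells to find the genes that answer the glucocorticoid. FKBP5 (ENSG00000096060), which codes for a chaperone of the glucocorticoid receptor, rose from 4.54 ± 0.409 RPKM (SD, n = 3) to 58.9 ± 2.80 (SD, n = 3), a log2 change of 3.43 ± 0.07 (SE; adjusted p = 1.93e-11). TSC22D3 (ENSG00000157514), the gene of the anti-inflammatory protein GILZ, rose from 5.19 ± 1.07 to 59.9 ± 2.59 (SD, n = 3 each). DEPP1 (ENSG00000165507), a regulator of autophagy, rose from 14.1 ± 0.292 to 199 ± 10.9 (SD, n = 3 each). Among the genes that fell, TNFRSF11B (ENSG00000164761), which codes for osteoprotegerin, went from 250 ± 15.9 to 20.1 ± 0.0992 (SD, n = 3 each), a log2 change of -3.57 ± 0.07 (SE). CCL2, the monocyte chemokine, went from 43.0 ± 2.05 to 6.87 ± 0.689 (SD, n = 3 each; adjusted p = 1.06e-09).

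At least 2-fold changes came to 148 genes higher and 122 lower, out of 2841 called by limma at any size (966 higher, 1875 lower). The lipoxygenase ALOX15B rose by 3.82 ± 0.11 (SE) to 16.3 ± 1.43 RPKM (SD, n = 3). RGCC, a cell cycle regulator, rose from 26.8 ± 0.269 to 225 ± 17.4 (SD, n = 3 each), and the inositol phosphatase IMPA2 from 4.70 ± 0.235 to 42.8 ± 1.05 (SD, n = 3 each). KLF15, a transcription factor that works with the glucocorticoid receptor, rose by 2.69 ± 0.12 (SE). CRISPLD2, a secreted protein, rose by 2.61 ± 0.07 (SE; adjusted p = 1.46e-10), and the clock gene PER1 by 2.59 ± 0.16 (SE; adjusted p = 1.68e-07). HSD11B1, whose enzyme regenerates active cortisol, rose from 1 ± 0.560 to 6.22 ± 0.946 (SD, n = 3 each). DUSP1, the gene of a MAP kinase phosphatase, rose from 80.3 ± 4.86 to 280 ± 13.9 (SD, n = 3 each), and ZFP36, which codes for an mRNA-destabilizing protein, by 0.87 ± 0.13 (SE). PTX3, the gene of a soluble pattern recognition protein, rose from 6.81 ± 1.38 to 32.6 ± 0.427 (SD, n = 3 each). The transcription factor CEBPD rose by 1.56 ± 0.20 (SE) and the NF-kB inhibitor NFKBIA by 1.42 ± 0.06 (SE).

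On the other side, KRTAP1-5, a keratin-associated protein, fell to 0.516 ± 0.112 RPKM (SD, n = 3), and RGMB, a bone morphogenetic protein co-receptor, from 115 ± 4.86 to 15.7 ± 0.432 (SD, n = 3 each). Both bradykinin receptors fell, BDKRB1 with a log2 change of -2.25 ± 0.08 (SE) and BDKRB2 with -2.10 ± 0.07 (SE). The hyaluronan synthase HAS2 fell from 42.2 ± 3.32 to 10.3 ± 0.168 (SD, n = 3 each), IER3 from 17.4 ± 3.86 to 3.31 ± 0.179 (SD, n = 3 each), and the AP-1 subunit JUN from 35.0 ± 1.54 to 11.9 ± 0.945 (SD, n = 3 each). NR3C1, the gene of the glucocorticoid receptor itself, fell by 1.01 on the log2 scale (adjusted p = 3.66e-06).

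The glucocorticoid-induced list rose nearly whole: 20 of 22 tested members were higher, RGS2, a regulator of G protein signalling, was lower, and FAM43A was neither (20 higher and 2 lower adjusted over the list alone; camera adjusted p = 1.89e-33, and 1.28e-05 with an estimated correlation). Its median log2 change was 1.97, with examples in ERRFI1 (2.31), MT1M (2.34), GLUL (2.05) and IRS2 (2.15). In the chemokine and cytokine list 8 of 12 fell, among them LIF (-2.13), IL6 (-1.56), CXCL8 (-1.01) and IL11 (-0.97), while TSLP rose (0.53); adjusted over the list alone 9 fell and 2 rose (adjusted p = 0.000707, and 0.0232 with an estimated correlation). The acute phase list had 4 of 7 higher, PTX3, STEAP4, NNMT and C1R (adjusted p = 0.000803, and 0.0232 with an estimated correlation). In the heat shock list 8 of 20 were lower, such as DDIT3 (-0.92) and HSPH1 (-0.47), and DDIT4 was higher (adjusted p = 0.037, and adjusted p = 0.085 with an estimated correlation). In the NF-kB list 9 of 22 fell, including IRF1 (-0.88) and ICAM1 (-0.77), and NFKBIA and SOD2 rose (adjusted p = 0.0785; 0.0451 with quantile normalization and 0.00284 with the GC and length trend removed).

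The remaining lists held genes that moved both ways or too little to pass. In the C/EBP and AP-1 list 7 of 19 rose, such as MYC (1.03) and KLF6 (0.88), and 5 fell, such as FOSL1 (-1.34) and EGR3 (-0.91), with an adjusted p of 0.303. In the prostanoid list 5 of 14 rose, including the receptor PTGER2 (1.84) and ALOX5AP (1.58), and 4 fell, including the phospholipase PLA2G4A (-0.78; list adjusted p = 0.0835). In the extracellular matrix list 6 of 25 rose, with the protease ADAMTS1 (1.64) and elastin ELN (1.07) foremost, and 6 fell, with HAS2 and TIMP3 (-0.63) foremost. In the contractile list 4 of 19 rose, VCL (0.90), DES, SYNM and MYOCD, and TPM1 (-0.48) and MYLK fell. The IL-17 receptor signalling list had 5 of 24 higher and 2 lower (adjusted p = 0.289), the MAP kinase phosphatase list 3 of 13 higher, among them DUSP5 (1.65), and 4 lower (0.334), and the clock list 2 of 14 higher and 3 lower (0.303). The interferon list had 4 of 13 lower, such as IFIT3 (-0.75), the cell cycle list 3 of 22 lower, and neither had a member higher. The fibroblast markers had 3 of 6 higher and 2 lower (0.303). In the C/EBP and AP-1, IL-17 receptor signalling and MAP kinase phosphatase lists the median change was negative (-0.125, -0.022 and -0.028) while the test statistic was positive. The lists for contractile genes, extracellular matrix, interferon response and cell cycle each had an adjusted p of 0.0835. Over all tested genes the median log2 change was -0.083, with 0.18 for the 10% of genes richest in GC and -0.23 for the 10% poorest. Quantile normalization moved the share of higher genes among those called from 34% to 48.5%. Leaving out 1 library gave 1718 to 2590 changed genes, 1718 without DEX 2 and 1827 without DEX 3.

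**Figure D2:**
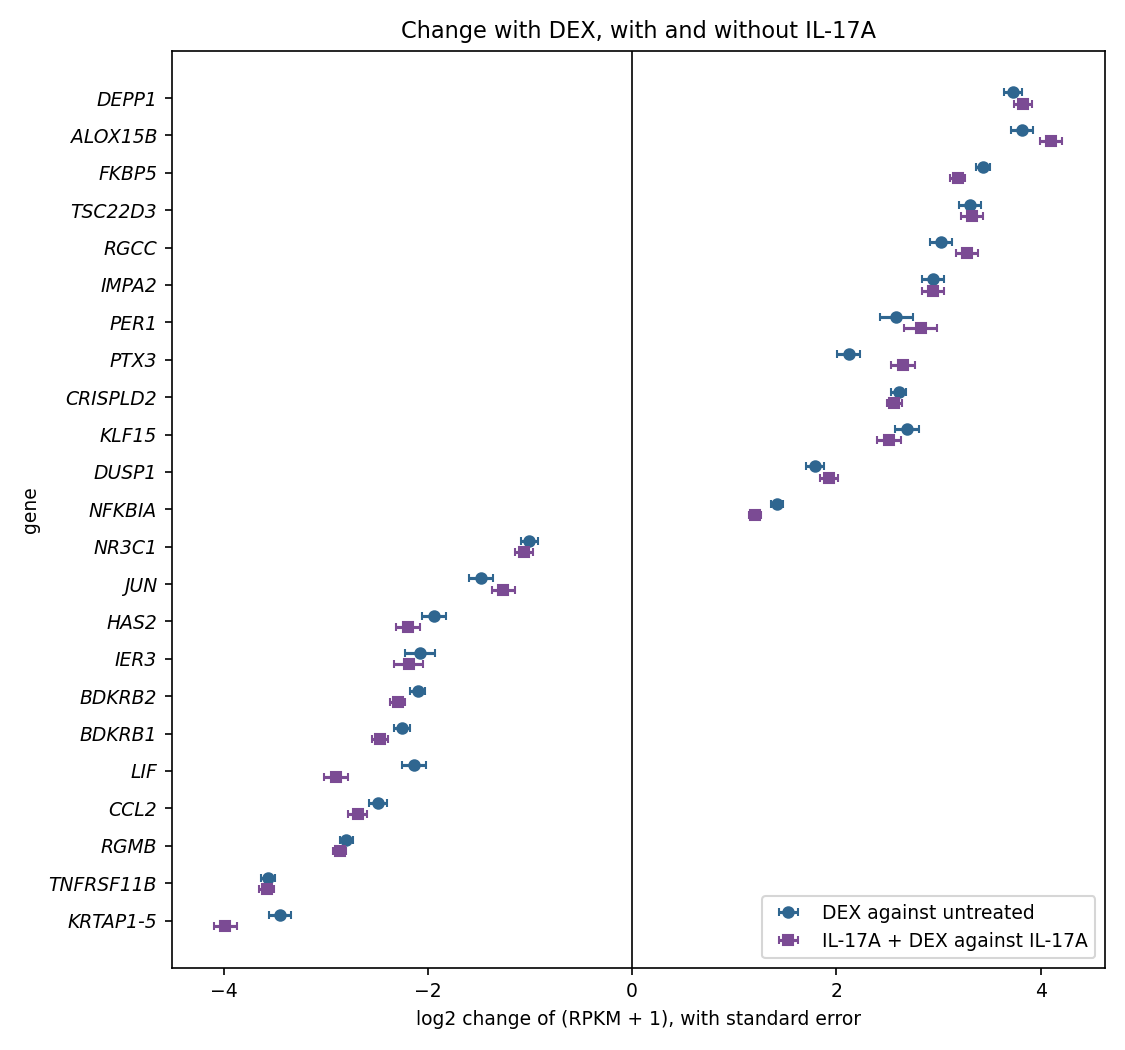
Log2 change of (RPKM + 1) with DEX for 23 genes, against untreated cells (circles) and, in cells also given IL-17A, against IL-17A alone (squares), with the SE from limma as bars (n = 3 libraries a group). FKBP5 changed by 3.43 and 3.19, TNFRSF11B by -3.57 and -3.58, and LIF by -2.13 and -2.90.

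IL-17A and DEX together were compared with IL-17A alone to ask what DEX does in cells that also receive the cytokine. The chemokines that IL-17A had raised were lower when DEX was present. CXCL8 was at 19.1 ± 3.48 RPKM (SD, n = 3) with IL-17A and at 2.34 ± 0.3 (SD, n = 3) with both, a log2 change of -2.58 ± 0.16 (SE; adjusted p = 1.60e-07). IL6 went from 12.4 ± 3.01 to 1.17 ± 0.130 (SD, n = 3 each; adjusted p = 1.08e-07), and CXCL1 from 92.6 ± 3.67 to 25.3 ± 2.01 (SD, n = 3 each; adjusted p = 5.59e-09). The steepest falls among genes raised by IL-17A were those of KRTAP1-5 (-3.98 ± 0.11, SE), LIF (-2.90 ± 0.12, SE) and CCL2 (-2.69 ± 0.09, SE). ZC3H12A, the RNase gene, stood at 12.3 ± 1.54 and 12.2 ± 0.995 (SD, n = 3 each; log2 change -0.01 ± 0.12, SE; adjusted p = 0.95).

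Of the 25 genes that IL-17A raised, 21 were lower with both treatments than with IL-17A alone, 3 were higher (NFKBIA, SOD2 and GPRC5B) and 1 was neither (ZC3H12A). Independent lists would give 6.3 lower and 3.5 higher. Since the IL-17A libraries enter both comparisons, libraries with no effect of DEX were simulated 100 times. Of a mean of 92.79 genes called raised by IL-17A there, 0.03 were lower on average, and at most 1. With no true effect of DEX on any gene, the adjustment leaves almost no calls, whereas the real comparison called 4977 of 12634 genes. The simulation therefore cannot tell how much sharing the libraries adds to the 21. Among the 21, CXCL6 had a log2 change of -2.27 ± 0.09 (SE), BDKRB2 of -2.30 ± 0.07 (SE), C3 of -0.74 ± 0.11 (SE) and NFKBIZ of -0.37 ± 0.08 (SE). DEX also lowered 12 of the 21 in cells without IL-17A, and raised all of the 3. The other 9 of the 21 were called lower only in cells with IL-17A, among them C3, CXCL3, NFKBIZ and SLC39A14, but none of the 9 passed the interaction test. Of the 5 genes that IL-17A lowered, 1 was lower still, 1 was higher and 3 were neither. Without untreated 1, untreated 2, untreated 3 or IL17A 3, 13 of the genes then called raised by IL-17A (17, 18, 16 and 16 in that order) were lower with both.

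At all sizes, 4977 genes differed between both treatments and IL-17A alone (1784 higher, 3193 lower), of which 188 were at least 2-fold higher and 160 at least 2-fold lower. Of the 4977, DEX had changed 2317 in cells without IL-17A too, 2315 of them in the same direction (847 higher, 1468 lower), where independent lists would share 1119.2. FKBP5 rose by 3.19 ± 0.07 (SE), TSC22D3 by 3.33 ± 0.11 (SE), PER1 by 2.82 ± 0.16 (SE) and DUSP1 by 1.93 ± 0.09 (SE). ZFP36, the mRNA-destabilizing protein gene, rose from 12.4 ± 2.46 to 32.8 ± 2.56 RPKM (SD, n = 3 each), and the receptor gene NR3C1 fell from 29.1 ± 3.97 to 13.4 ± 0.896 (SD, n = 3 each). In the fixed lists, 9 of 12 chemokine and cytokine genes fell and TSLP rose (median log2 change -1.85; camera adjusted p = 1.92e-06, and 0.00467 with an estimated correlation), and 20 of 22 glucocorticoid-induced genes rose (1.93e-25, and 3.72e-05 with an estimated correlation). In the cell cycle list 11 of 22 fell, with AURKA (-0.67) and CDK1 (-0.55) as examples, 14 adjusted over the list alone (0.0239; adjusted p = 0.174 with an estimated correlation). The acute phase list, with 4 of 7 higher and C3 lower (0.0243), and the contractile list, with 5 of 19 higher and 2 lower (0.043; 0.403 with the GC and length trend removed), gave adjusted p = 0.115 and 0.217 with an estimated correlation. In the NF-kB list 11 of 22 fell and 2 rose (0.122; 0.00114 with the GC and length trend removed), and in the heat shock list 12 of 20 fell and 3 rose (0.0728; 0.000459 with that trend removed). In the interferon list 7 of 13 fell (0.25). The share of higher genes among those called moved from 35.8% to 46% with quantile normalization, and the median log2 change was -0.082 over all genes, 0.38 for the 10% richest in GC and -0.33 for the 10% poorest. With the GC and length trend removed from each library, 3261 genes were called (1695 higher, 1566 lower). Of those called without this step, 309 had the opposite sign of change after it, whether still called or not. The count fell to 3131 without IL17A_plus_DEX 3 and to 3218 without IL17A_plus_DEX 2, and reached 5948 at most.

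Both treatments against untreated cells show the net result. CXCL1 stayed above its untreated level at 25.3 ± 2.01 RPKM (SD, n = 3; log2 change 2.62 ± 0.08, SE; adjusted p = 2.63e-10), as did NFKBIZ (at 19.1 ± 0.427, SD, n = 3), ZC3H12A (2.01 ± 0.12, SE), SOD2 (1.77 ± 0.08, SE) and CXCL6 (0.59 ± 0.09, SE). CXCL8 had a log2 change of 0.15 ± 0.16 (SE; limma adjusted p = 0.473). IL6 (-1.10 ± 0.15, SE), LIF (-1.92 ± 0.12, SE) and CCL2 (-1.77 ± 0.09, SE) lay below the untreated level. PTX3, the pattern recognition gene, was highest here, at 57.9 ± 2.21 RPKM against 6.81 ± 1.38 untreated (SD, n = 3 each), and CCN4, a matricellular growth regulator, rose by 2.56 ± 0.08 (SE). The kinase gene PLK2 fell from 51.9 ± 1.21 to 12.3 ± 0.612 (SD, n = 3 each), and DIO2, which codes for a thyroid hormone activating enzyme, from 25.6 ± 2.13 to 5.70 ± 0.221 (SD, n = 3 each). In total 4794 genes changed (1493 higher, 3301 lower; 175 and 144 at least 2-fold), with a median log2 change of -0.101 over all tested genes. With the GC and length trend removed, 3147 were called (1675 higher, 1472 lower). Of the 4794, 244 then had the opposite sign of change, whether still called or not. The share of higher genes moved from 31.1% to 45.8% with quantile normalization. The glucocorticoid-induced list (20 of 22 higher; camera adjusted p = 2.01e-27) and the acute phase list (5 of 7 higher; 0.000119) passed with either correlation, while 5 of 12 chemokine and cytokine genes were higher and 5 lower (0.593), with a median log2 change of -0.086 although the test statistic was positive. Without untreated 2 the count was 3082, and without IL17A_plus_DEX 3 it was 3108.

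IL-17A in the presence of DEX was measured as both treatments against DEX alone. Here 10 genes rose and 0 fell, 6 of them at least 2-fold, and 601 genes had an unadjusted p under 0.05 by limma. CXCL1 rose from 1.39 ± 0.125 to 25.3 ± 2.01 RPKM (SD, n = 3 each; log2 change 3.46 ± 0.08, SE; adjusted p = 1.19e-10). NFKBIZ rose by 2.20 ± 0.08 (SE), ZC3H12A by 1.91 ± 0.12 (SE), SOD2 by 1.40 ± 0.08 (SE), CXCL6 by 1.25 ± 0.09 (SE), CXCL8 by 1.16 ± 0.16 (SE) and C3 by 1.00 ± 0.11 (SE). CCL2 rose by 0.72 ± 0.09 (SE) and SLC39A14 by 0.40 ± 0.06 (SE), which makes 9 of the 10 genes also raised by IL-17A without DEX. The last was PTX3, which went from 32.6 ± 0.427 to 57.9 ± 2.21 (SD, n = 3 each; adjusted p = 0.0154); without DEX its log2 change with IL-17A was 0.28 ± 0.11 (SE; limma adjusted p = 0.733), and the difference between these changes was 0.53 ± 0.16 (SE; adjusted p = 0.881). The calls of PTX3 and SLC39A14 were lost in each fit without 1 library of these groups. These fits kept 6 to 8 of the 10 calls, so most of them lost others as well. IL6 was at 0.586 ± 0.237 and 1.17 ± 0.130 (SD, n = 3 each; limma adjusted p = 0.801).

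The chemokine and cytokine list again moved most with IL-17A, with 4 of 12 members higher, 8 adjusted over the list alone (camera adjusted p = 3.66e-20, and 0.000126 with an estimated correlation). In the NF-kB list NFKBIZ and SOD2 rose, 9 adjusted over the list alone (5.99e-14, and 0.000202 with an estimated correlation), and in the acute phase list C3 and PTX3 rose (0.00166, and 0.0304). The IL-17 receptor signalling list, with ZC3H12A as its 1 called member, passed at 0.0131, and the C/EBP and AP-1 list, with 0 members called, at 0.0326; these gave adjusted p = 0.11 and adjusted p = 0.782 with an estimated correlation, and the latter 0.602 with the GC and length trend removed. Without DEX 3 the count of changed genes was 6.

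**Figure D3:**
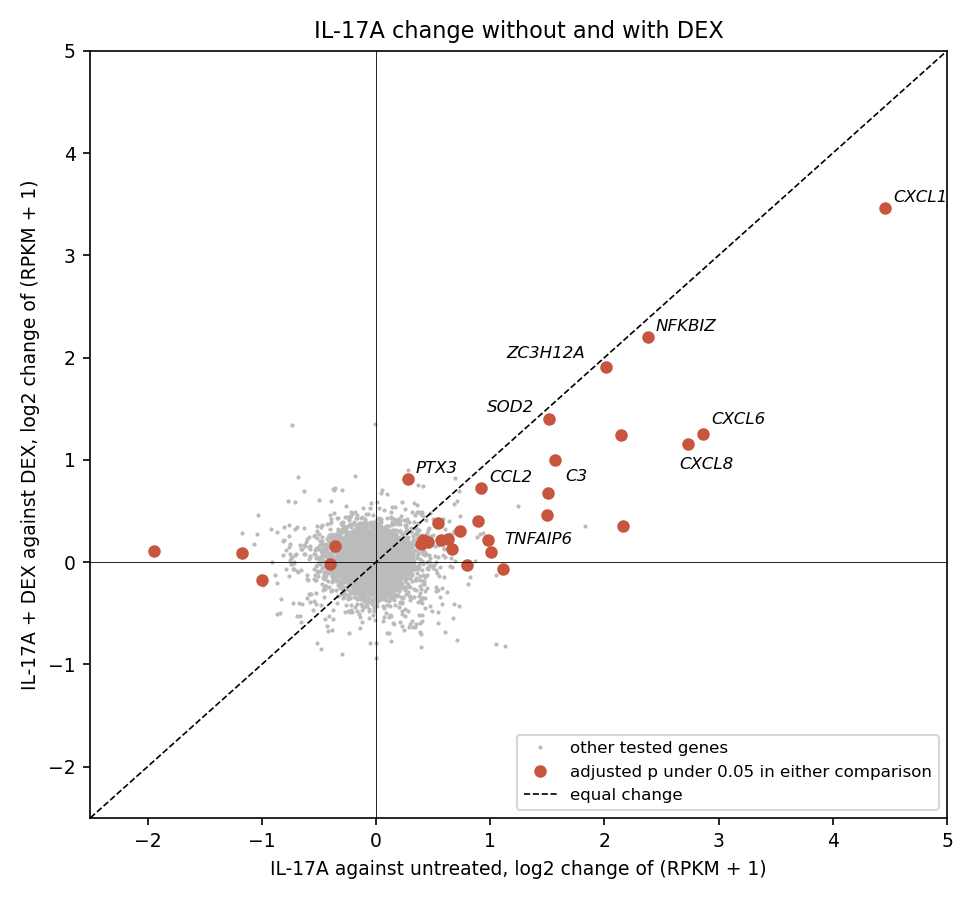
Log2 change of (RPKM + 1) with IL-17A without DEX (horizontal) and with DEX (vertical) for the 12634 tested genes, with genes at an adjusted p under 0.05 in either comparison as large points and equal change as a dashed line. CXCL1 lies at 4.45 and 3.46, and ZC3H12A at 2.02 and 1.91.

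The interaction tested whether the change with IL-17A differed with and without DEX. By limma 6 genes passed, 4 with a lower and 2 with a higher value under DEX; with 1 library left out the count was 2 without untreated 1, untreated 3, IL17A 3 or DEX 2, 3 without untreated 2, DEX 1, DEX 3 or IL17A_plus_DEX 3, and 10 without IL17A 2. CXCL6 rose by 2.86 without and by 1.25 with DEX, a difference of -1.61 ± 0.13 (SE; adjusted p = 4.58e-04). CXCL8 rose by 2.73 and 1.16, a difference of -1.57 ± 0.23 (SE; adjusted p = 0.0304), and CXCL1 by 4.45 and 3.46, a difference of -0.99 ± 0.11 (SE; adjusted p = 0.0073). TNFAIP6, the hyaluronan-binding protein gene, differed by -0.91 ± 0.13 (SE; adjusted p = 0.0304), NEAT1 by 0.51 ± 0.07 (SE) and the unnamed ENSG00000268656 by 2.06. For NFKBIZ (-0.18 ± 0.11, SE), ZC3H12A (-0.10 ± 0.17, SE) and SOD2 (-0.11 ± 0.11, SE) the adjusted p-values were 0.881, 0.902 and 0.881. In the chemokine and cytokine list 3 of 12 members had a lower and 0 a higher change under DEX, 8 and 1 adjusted over the list alone (camera adjusted p = 1.22e-14, and 0.000425 with an estimated correlation). With a pseudocount of 0.1 limma called 0 genes (614 at an unadjusted p under 0.05), and limma-voom on recovered reads, chosen after seeing the data, called 1, NEAT1 (558 unadjusted). In these fits the difference was -1.43 ± 0.18 and -1.40 ± 0.28 (SE) for CXCL6, -1.08 ± 0.40 and -1.19 ± 0.47 (SE) for CXCL8, -0.69 ± 0.13 and -0.67 ± 0.24 (SE) for CXCL1, and -0.95 ± 0.18 and -0.88 ± 0.27 (SE) for TNFAIP6. The list passed in both, at 3.1e-07 and 0.000239.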

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

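The interaction test was planned; the tests that weigh explanations in this part were chosen after the result was seen, except that what to look for was written before the result for the sum outside the 100 most abundant genes, for the GC trend between libraries that lie apart, and for voom weights, although the fits with voom and with the trend removed were chosen after seeing the data.

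The change with IL-17A differed between cells with and without DEX for 6 genes, by limma's interaction test at a Benjamini-Hochberg adjusted p under 0.05 (2 to 10 with 1 library left out). The change under DEX minus that without, on the log2 scale, was -1.61 for CXCL6, -1.57 for CXCL8, -0.99 for CXCL1 and -0.91 for TNFAIP6, and 0.51 for NEAT1 and 2.06 for ENSG00000268656. The latter has no symbol in the tables used, and its call rests on values that were lower with IL-17A, with DEX and with both alike than in untreated cells.

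Chemokines and cytokines rose less with IL-17A when DEX was present, with a median interaction of -0.796 over the 12 tested members of the fixed list. A pseudocount of 1 shrinks changes of low values, but at 0.1 the median was still -0.727. Counting noise at few reads does not remove the pattern, since voom weights left the list at a camera adjusted p of 0.000239. No single gene of the list passed in either of those fits, where the SE was larger: CXCL6 went from -1.61 ± 0.13 (SE) to -1.43 ± 0.18 and -1.40 ± 0.28, and CXCL1 from -0.99 ± 0.11 to -0.69 ± 0.13 and -0.67 ± 0.24. One hypothesis is that DEX may lower how far IL-17A can raise these transcripts; it was found and tested on the same libraries, and other times and doses are not in these data.

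More genes were lower than higher with DEX at any size of change, 1875 against 966. Among changes of at least 2-fold the balance was the reverse, with 148 higher and 122 lower. With the GC and length trend removed 54.4% of the called genes were higher, and with quantile normalization 48.5% were. Both steps also centre the libraries (median log2 change -0.004 and -0.026), which by itself evens out higher and lower, so neither share decides whether GC response or scaling is the source of the excess. A larger share taken by the most abundant genes would lower all others alike, but the genes outside the 100 most abundant changed in sum by only -0.022 on the log2 scale, against a median of -0.083. Both stay open, because DEX and the GC trend go together in these groups.

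Libraries of the IL-17A and untreated groups lay apart, IL17A 2 from IL17A 1 and untreated 2 from untreated 1, along a component that held 40.9% of the variance within groups among genes with GC content. After removal of the GC and length trend the first component held 21.1%, which is consistent with a GC trend between libraries. Depth argues against being the cause, since over the 12 libraries the distance from the group mean in depth and that along the first component had a Spearman correlation of -0.32. The labels give no batch, and no biological explanation was tested.

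Other splits of the same 6 libraries gave far fewer changed genes: for IL-17A against untreated 1 at most where the real split gave 30, for DEX against untreated 11 against 2841, for both against untreated 0 against 4794, for both against IL-17A 0 against 4977, and for both against DEX 0 against 10. In each case only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each other split also mixes libraries of the compared groups, so any effect of the treatment widens the spread within its groups and lowers its count. The low counts are therefore not a level that chance alone would give. For the interaction, 3 of 100 regroupings of the 12 libraries gave at least 6 genes, the real one included, with 2980 as the highest other; these regroupings move the effect of DEX itself, so they do not test the interaction. With the effects of IL-17A and DEX kept and the residuals exchanged, 2 of 100 gave as many, the real one included, with 1273 as the highest other. What sets the exchange with 1273 genes apart was not tested.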

How the results depend on the processing

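The fits with limma-voom, with the GC and length trend removed, and without IL17A 2 and untreated 2 together were chosen after seeing the data; the rest were planned. Counts were compared, as were passing lists (by estimated correlation, fry, block and 1 library left out). Of planned results 160 kept their side of the threshold (a count within 1.5 times), 56 became weaker and 1 stronger. Of the added ones 11 kept it, 4 became weaker and 4 stronger. For named genes planned numbers were 6532, 178 and 11, the added ones 1256, 33 and 14. Uncalled genes may have changed sign. Planned fits meant for counts in other packages were not run, because the deposited values are not counts.

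At an adjusted p under 0.01 the counts were 17 for IL-17A against untreated, 1472 for DEX against untreated, 2455 for both against untreated, 2524 for both against IL-17A and 2 for the interaction. At a fold of at least 2 they were 15, 270, 319 and 348, 6 for both against DEX and 3 for the interaction. The stricter filter gave 16 for IL-17A and 3 for the interaction. Fits of only the groups compared gave 14 for IL-17A and 3217 for both against IL-17A. The interaction gave 0 genes at a pseudocount of 0.1, 1 by limma-voom and 3 without IL17A 2 and untreated 2. With the GC and length trend removed the counts were 97 for IL-17A, 3147 for both against untreated, 3261 for both against IL-17A, 16 for both against DEX and 10 for the interaction, and 47 genes raised by IL-17A were lower with both. In that fit 244 and 309 genes called without that step in both against untreated and in both against IL-17A had the opposite sign of change, whether still called or not. The cause was not tested.

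Leaving out 1 library gave 17 to 36 genes for IL-17A against untreated (19 without untreated 1 or IL17A 3, 17 without untreated 3), 1718 to 2590 for DEX against untreated (1718 without DEX 2, 1827 without DEX 3), 3082 to 4652 for both against untreated (3082 without untreated 2, 3108 without both 3), 3131 to 5948 for both against IL-17A (3218 without both 2, 3131 without both 3) and 6 to 8 for both against DEX (6 without DEX 3). For the interaction it gave 2 to 10 (2 without untreated 1, untreated 3, IL17A 3 or DEX 2; 3 without untreated 2, DEX 1, DEX 3 or both 3; 10 without IL17A 2). Of the genes raised by IL-17A, 13 to 20 were lower with both (13 without untreated 1, 2 or 3 or IL17A 3). The cause was not tested.

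List tests that passed in the report were weaker in these cases, as adjusted p-values. With an estimated correlation, IL-17A gave 0.0854 for prostanoid and 0.216 for cell cycle genes, DEX gave 0.085 for heat shock genes, both against IL-17A gave 0.115 for acute phase, 0.217 for contractile and 0.174 for cell cycle genes, and both against DEX gave 0.11 for IL-17 receptor signalling and 0.782 for C/EBP and AP-1 genes. By fry, which does not compare a list with other genes, the cell cycle list after IL-17A gave 0.336, and under DEX IL-17 receptor signalling gave 0.055 and C/EBP and AP-1 gave 0.842. Leaving out 1 library gave for IL-17A 0.000934 to 0.065 for acute phase, 0.0227 to 0.146 for prostanoid and 0.0138 to 0.298 for cell cycle genes; 0.0147 to 0.0812 for heat shock with DEX; 0.0262 to 0.0895 for contractile genes in both against IL-17A; and 0.00587 to 0.0692 and 0.00587 to 0.388 for IL-17 receptor signalling and for C/EBP and AP-1 in both against DEX. Lists that had not passed did so with some library left out: for IL-17A, C/EBP and AP-1 (0.00367), fibroblast markers (0.00768), IL-17 receptor signalling (0.0227) and clock genes (0.0442); NF-kB with DEX (0.0287); NF-kB (0.0177) and heat shock (0.0115) in both against IL-17A; and cell cycle in the interaction (0.0428). By fry most lists passed in the comparisons with DEX against no DEX, such as NF-kB with DEX (0.000346). Other settings also moved calls. Quantile normalization gave 0.0622 for cell cycle and 0.0435 for clock genes with IL-17A, 0.0451 for NF-kB with DEX and 0.0825 for contractile genes in both against IL-17A. A pseudocount of 0.1 gave 0.0496 for clock genes with IL-17A, and limma-voom gave 0.0613 for heat shock with DEX and 0.0835 for contractile genes in both against IL-17A. With the GC and length trend removed NF-kB gave 0.00284 with DEX and 0.00114 in both against IL-17A, heat shock gave 0.00291 in both against untreated and 0.000459 in both against IL-17A, contractile genes gave 0.403 in both against IL-17A, C/EBP and AP-1 gave 0.602 in both against DEX, and prostanoid and cell cycle genes gave 0.0301 each in the interaction. The cause was not tested.

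The replicate number as a block gave 25, 2343, 4230, 4359, 9 and 4 changed genes in the order above. After group means were removed, libraries with the same number in different groups correlated, across genes, at 0.38, 0.4 and 0.06 for IL-17A with untreated but at -0.26, -0.21 and -0.09 for DEX with untreated, so the numbers were not taken to pair samples. Depth limits genes of few reads: CSF3 had 5 reads in all with IL-17A and 9 with both, and 0 in the other groups.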

Other observations

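The correlation of DEX changes in this part was a test chosen after the result was seen; the fit with no filter on low values was planned.

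Below the filter, SAA1, SAA2, LYZ and SERPINA3, picked after their values were seen, were highest with both treatments in the fit with no filter (limma, Benjamini-Hochberg adjusted). Other low genes of host defence were not called for both against untreated, such as HP (adjusted p = 0.724), CP (0.614) and CHI3L1 (0.323). SAA1, which codes for the acute phase protein serum amyloid A, was at 0.0904 ± 0.157 RPKM (SD, n = 3) in untreated cells, 0.336 ± 0.31 with IL-17A, 0.234 ± 0.0438 with DEX and 1.2 ± 0.569 with both, a log2 change of 0.99 ± 0.21 (SE) for both against untreated (adjusted p = 0.0119). Its close paralog SAA2 was listed at 0 in 3 groups and at 0.214 ± 0.15 (SD, n = 3) with both, and reads of the pair can be exchanged. LYZ, the lysozyme gene, was at 0 with no addition and with IL-17A, 0.0166 ± 0.0288 with DEX and 0.579 ± 0.304 with both (adjusted p = 0.00412 against untreated). SERPINA3, a protease inhibitor of the acute phase, was at 0.0599 ± 0.0356, 0.0385 ± 0.0475, 0.359 ± 0.00885 and 0.514 ± 0.0724 in the same order (adjusted p = 0.000115). Against DEX alone the adjusted p-values were 0.786 for SAA1, 0.703 for SAA2, 0.261 for LYZ and 0.916 for SERPINA3, and the interactions of these 4 genes had adjusted p = 0.853.

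Among other low cytokine genes, CSF2, IL1B and CXCL2 were called lower with both treatments than with IL-17A, and CXCL5 was not (adjusted p = 0.871). CSF2, the gene of granulocyte-macrophage colony-stimulating factor, was at 1.15 ± 0.226 RPKM with IL-17A and listed at 0 with both (SD, n = 3 each; log2 change -1.10 ± 0.14, SE; adjusted p = 0.000816), and IL1B went from 0.39 ± 0.127 to 0 (adjusted p = 0.00101). CXCL5, a neutrophil chemokine, was at 0.197 ± 0.0467 untreated, 0.823 ± 0.138 with IL-17A, 0.393 ± 0.132 with DEX and 0.888 ± 0.211 with both (SD, n = 3 each; adjusted p = 0.00346 for both against untreated). CXCL2 was at 0.215 ± 0.161, 0.99 ± 0.194, 0.0838 ± 0.0812 and 0.328 ± 0.207 in that order (limma adjusted p = 0.0158 for both against IL-17A). For IL-17A against untreated the limma adjusted p-values of CSF2, IL1B, CXCL5 and CXCL2 were 0.225, 0.124, 0.138 and 0.15. ZBTB16, a glucocorticoid-induced transcription factor, was at 0.00564 ± 0.00977 untreated and 0.282 ± 0.0402 with DEX (adjusted p = 0.0002), and the interferon response gene IFI44L at 0.222 ± 0.0566 and 0.769 ± 0.161 (adjusted p = 0.00316), unlike the tested members of its list. CSF3, the granulocyte colony-stimulating factor gene, had 0 reads in every untreated and DEX library, 5 in the 3 IL-17A libraries and 9 in the 3 with both. In all, genes below the filter of the tests gave 11 calls for IL-17A, 242 for DEX, 366 for both against untreated, 343 for both against IL-17A, 4 for both against DEX and 5 for the interaction.

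A hypothesis for the genes raised by IL-17A is that DEX acts on them whether or not IL-17A is present. Across these 25 genes the change with DEX in cells with IL-17A and that in cells without had a Spearman correlation of 0.92 (Pearson 0.92). This is consistent with the hypothesis, but it is a correlation across genes, which are not independent replicates, and each change is measured against its own group of 3 libraries. A correlation also leaves out any offset: all 25 genes had a lower change with DEX in cells with IL-17A than without, for example CXCL6 (-2.27 against -0.66), IL6 (-2.60 against -1.56) and KRTAP1-5 (-3.98 against -3.45). Of the 25, CXCL1, CXCL6, CXCL8 and TNFAIP6 passed the interaction test, so the presence of IL-17A went with a different size of change for these. The 25 were selected by high values in the IL-17A libraries, which by itself lowers their change from that group.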
